A study of Glycine max with 34 samples.

How the data were processed

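Small RNA was measured by sequencing in 34 libraries from 17 subregions of soybean seeds at the early maturation stage, each subregion with 2 biological replicates. Per the labels, plants were grown in a greenhouse, seeds 6 to 7 mm long were fixed in ethanol and acetic acid and embedded in paraffin, and the subregions were captured from sections with a laser. Libraries were made with a small RNA kit and 15 PCR cycles, from 250 ng of RNA in 31 libraries and from 50 ng in 3 (both shoot apical meristem libraries and seed coat palisade 1). The labels do not say how many plants or seeds were pooled, nor which subregions came from the same plants, so captured regions may share plants and p-values over them may be too small.

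Each deposited file gives, for 1 library, a count for every distinct sequence of 18 to 26 nt. The unit is the raw read count per sequence as deposited, with sequences counted a single time kept. Bowtie is named in the submitters' processing notes. Its role and version, the genome build, and the steps for adapter removal and filtering are not given in the sources used here. Group and replicate were taken from the sample titles. For the 4 cotyledon adaxial samples the tissue tag in the labels says abaxial, and the titles were followed. No genome or transcript annotation was at hand, so sequences carry no positions. The planned test of small RNAs matching chalcone synthase transcripts was not analysed here for the same reason.

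A sequence was assigned to a microRNA family when it contained a 17-base core, bases 2 to 18 of a mature sequence, and the counts of a family were summed. The list held 58 mature sequences in 45 families, written from general knowledge of plant microRNAs. The families were grouped into 6 lists fixed before any value was seen (development, auxin, nutrient, phasiRNA triggers, small RNA pathway, and other legume families). A core also collects length variants and offset forms, and it cannot tell members of a family apart. Families with at least 1 CPM (counts per 1e+06 of the file total) in at least 2 libraries were tested, which left 39. Single sequences with at least 5 CPM in at least 2 libraries were tested, which left 32538. The lists, contrasts, tests, filters and the rule for naming items were chosen before the data were examined.

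Counts were fitted with edgeR 4.0.16 in R 4.3.3, with a mean for each of the 17 subregions and a quasi-likelihood F test. All 34 libraries shared 1 estimate of the spread on 17 residual degrees of freedom. Library sizes were the file totals, and trimmed mean of M values (TMM) factors came from the sequence table and served both tables; they ran from 0.588 to 1.53. Adjusted p-values are Benjamini-Hochberg values over all items of a table, and a value under 0.05 counts as passed. A contrast averages the subregion means on the log scale, so a fold is a ratio of geometric means and can differ in size from a ratio of the mean CPM. Rose and fell refer to the first-named side of a contrast. CPM levels of families are TMM-scaled means over subregions. SE is the log2 change divided by the square root of F. There were 7 contrasts (seed coat against embryo, axis against cotyledon, endosperm against embryo, epidermis against parenchyma, vasculature against parenchyma, shoot against root tip, and adaxial against abaxial cotyledon). The embryo is the axis and the cotyledons together. Epidermis was compared with parenchyma within axis, abaxial and adaxial cotyledon, and vasculature with parenchyma within axis and cotyledon. Up to 15 families that rose and 15 that fell, up to 4 members of each list, and the 3 sequences with the largest rise and fall at 50 CPM or more were open to naming in each contrast. Sequences that held a family core, or overlapped a named sequence by 15 bases, were left out of that naming. The share of counts in each length class and in all families was compared between organs by two-sided exact permutation tests over subregion means, adjusted over 8 tests.

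Where a family or sequence had no count in either library of a subregion, the log-scale mean of that subregion has no lower bound. Of the 39 families, 12 had such a subregion in the seed coat contrast, and 9 of the 27 that passed did (miR169, miR393, miR394, miR395, miR399, miR862, miR1513, miR2111 and miR2119). In the axis contrast 3 of 21 did (miR397, miR399 and miR1513), and for endosperm 4 of 23 did (miR397, miR1513, miR2111 and miR2119). For epidermis 1 of 5 did (miR2109) and for vasculature 1 of 7 (miR394). Their printed fold depends on the prior count added to each value. An item with such a subregion on both sides was outside the test's reach, and its adjusted p near 1 carries no information. Among the 39 families this held for 3 in the seed coat contrast, 7 for axis and 3 for endosperm. It held for 6 for epidermis, 4 for vasculature, 4 for shoot and 3 for the cotyledon faces. Counts given out of 39 families, or out of the members of a list, still include such families. Among all items that passed, 0 had the empty subregion on their higher side. Of the sequences that passed, between 29.9% (axis contrast) and 45.5% (endosperm) had an empty subregion. Items with 10 or fewer counts on a side are given as a ratio of unscaled CPM with an exact 95% counting interval.

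A library's total ran from 2341506 to 11697518 counts. A floor of 3 counts corresponds to 1.28 CPM in the shallowest and 0.256 CPM in the deepest library. Reads carried no molecular identifiers, so floors and intervals cover counting error only. In a test on simulated data, 200 of the 32538 sequences were changed in the seed coat contrast. Of 100 changed 2-fold 11 were recovered, of 100 changed 4-fold 68 were recovered, and 8 of the others were called. Unchanged sequences had 1 mean over all libraries there, with no spread between subregions and no missing starts. The 8 calls are therefore no measure of false calls in the real contrast, where other groupings of the subregions gave a median of 1817 sequences. In the adaxial contrast 0 and 13 of 100 were recovered, and in the epidermis contrast 0 and 11. Of 4 families changed 2-fold in the seed coat contrast 3 were recovered, and 4 of 4 changed 4-fold.

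Each result was recomputed with other settings: relative log expression (RLE) factors, library totals alone, DESeq2 1.42.0, other minimum levels (2 and 20 CPM, or none for families), the style of the deposited file name as a covariate, a replicate block, no 50 ng libraries, and each library left out in turn. Organ contrasts were also tested with limma 3.58.1 on subregion means, which takes the subregions as the replicates. For a list, a count adjusted over the list alone is given. Further settings were chosen after checks of the files: leaving out 1 of 2 near-identical libraries, leaving out 5 libraries with 10 or more counts per distinct sequence, fitting families together with sequences, leaving out sequences with missing starts, entering start composition as an offset, and leaving out 14 libraries with missing starts.

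Those checks found the following. Cotyledon adaxial epidermis 1 and cotyledon adaxial parenchyma 1 differed by little more than counting noise (chi-square per degree of freedom 1.50), while the 17 replicate pairs lay at 20.8 or more. The deposited name of the former carries the parenchyma code. Replicates correlated at r = 0.678 to 0.949 across sequences, which are not independent replicates, and 21 of 34 libraries were closest to their own replicate. The first 6 bases of each sequence were compared between libraries. A start was called missing where its distinct sequences numbered under 10% of those expected from the median library. In 14 libraries between 24 and 238 starts were missing in this sense, as drawn in the plot of missing starts. TCGGAC, the start of the miR166 form that begins with TCGG, was missing from axis parenchyma 1 (0.0764 of the expected number) and thinned in seed coat parenchyma 1 and 2 (0.108 and 0.119). miR166 is therefore understated in axis parenchyma 1, and perhaps in seed coat parenchyma, where the amount is not known. The files do not say why starts are missing. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for counting, permutation tests and plots.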

Results

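Small RNA was sequenced from laser-captured subregions of soybean (Glycine max) seeds at the early maturation stage. The embryonic axis gave 7 subregions in 14 libraries: epidermis, parenchyma, vasculature, stele (the central cylinder), plumule (the embryonic shoot with its first leaves), shoot apical meristem and root tip. The cotyledons gave 5 subregions in 10 libraries: epidermis and parenchyma of the abaxial, outer face and of the adaxial, inner face, and vasculature. The seed coat gave 4 subregions in 8 libraries: palisade, hourglass cells, parenchyma and hilum (the scar where the seed was attached). The endosperm gave 1 subregion in 2 libraries. Each library held 2341506 to 11697518 counts, with a median of 3992253, over 303746 to 2994835 distinct sequences of 18 to 26 nt.

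The microRNA families took up 17.2% of all counts. miR166, which represses class III homeodomain-leucine zipper genes, made up 83.2% of the family counts and had a mean level of 148273 CPM ± 161061 (SD, n = 34 libraries). It was followed by miR1507 at 6439.5 CPM ± 3534, miR159, which represses GAMYB-like genes, at 5892 CPM ± 3784, and miR482 at 4442 CPM ± 2604. miR2118 at 2017 CPM, miR1511 at 1646.5 CPM, miR319 at 1617 CPM, miR390 at 1505 CPM, miR156/miR157 at 1118 CPM and miR398 at 858 CPM completed the 10 highest. Of the 45 families looked for, 6 were below the level filter. miR172, which represses AP2-like genes, had 40 counts over all libraries, miR828 had 11, miR4415 had 6 and miR1535 had 4. miR827 and miR530 had 0 counts, which allows up to 0.0167 CPM each over all libraries for sequences that hold the cores used. Forms without such a core were not counted, so this sets no limit on the families themselves. Sequences with the start of the TCGG form of miR166 were thinned in several libraries, most of all in axis parenchyma 1 and both seed coat parenchyma libraries. Among 23- and 24-nt sequences this start also stood at 0.472 and 0.387 of its expected share in axis epidermis 1 and 2. It stood at 0.496 in palisade 2 and 0.547 in endosperm 2, so miR166 may be understated there too. The thinning leaves miR166 understated in axis parenchyma 1, whose replicate held 345894 counts of the TCGG form against 101. In seed coat parenchyma it is not known how much, if any, was lost.

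The first question was how the organs differ in small RNA length, since 21-nt sequences include most plant microRNAs and 24-nt sequences are the class tied to RNA-directed DNA methylation. The seed coat was richest in 21-nt counts, at 37.4% ± 9.74 (SD, n = 4 subregions) against 18.4% ± 8.53 (n = 12) in the embryo. The axis was richest in 24-nt counts, at 52.8% ± 9.88 (n = 7) against 33.9% ± 5.42 (n = 5) in the cotyledons, and every axis subregion lay above every cotyledon subregion. The cotyledons held more 22-nt counts, at 12.3% ± 1.75 against 8.85% ± 1.76 in the axis. The shoot apical meristem stood at the far end with 69.1% ± 0.847 (SD, n = 2) of 24-nt counts, 4.86% ± 0.0882 of 21-nt counts and 1.32% ± 0.319 of family counts. Both its libraries, and no other axis library, were made from 50 ng, so subregion and RNA input cannot be told apart there. Seed coat palisade held the largest family share, 47.1% ± 14.7 (n = 2), and the endosperm held 3.07% ± 1.03. The palisade mean joins 57.5% in palisade 1, made from 50 ng, and 36.7% in palisade 2, made from 250 ng.

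In two-sided exact permutation tests over subregion means, the 21-nt difference between seed coat and embryo (adjusted p = 0.0176), the 24-nt difference between axis and cotyledon (adjusted p = 0.0176) and the 22-nt difference between axis and cotyledon (adjusted p = 0.0404) passed. By chance all axis subregions lie above all cotyledon ones in 0.126% of groupings. The 24-nt share of seed coat and embryo (32.9% and 44.9%, adjusted p = 0.187), their 22-nt share (11.3% and 10.3%, adjusted p = 0.605) and their family share (24.6% and 15.2%, adjusted p = 0.294) did not pass in the exact test. Nor did the 21-nt share of axis and cotyledon (17.2% and 20.1%, adjusted p = 0.693) or their family share (15.3% and 15.0%, adjusted p = 0.982). Subregions cut from the same plants would make these p-values too small. Sequences of 18, 19, 25 and 26 nt made up 13.01% ± 3.17 of counts in the axis, 22.9% ± 2.88 in the cotyledons, 11.47% ± 3.93 in the seed coat and 28.6% ± 0.258 in the endosperm (n = 2 libraries). Fragments of 5S ribosomal RNA made up 5.39% ± 1.98 in the axis, 10.6% ± 2.82 in the cotyledons, 7.54% ± 6.26 in the seed coat and 16.9% ± 3.21 in the endosperm. Without the 50 ng libraries the 22-nt difference was -3.12 percentage points and did not pass the exact test. It did not pass either without axis parenchyma 2 (-3.23) or without cotyledon vasculature 2 (-3.09).

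**Figure D1:**
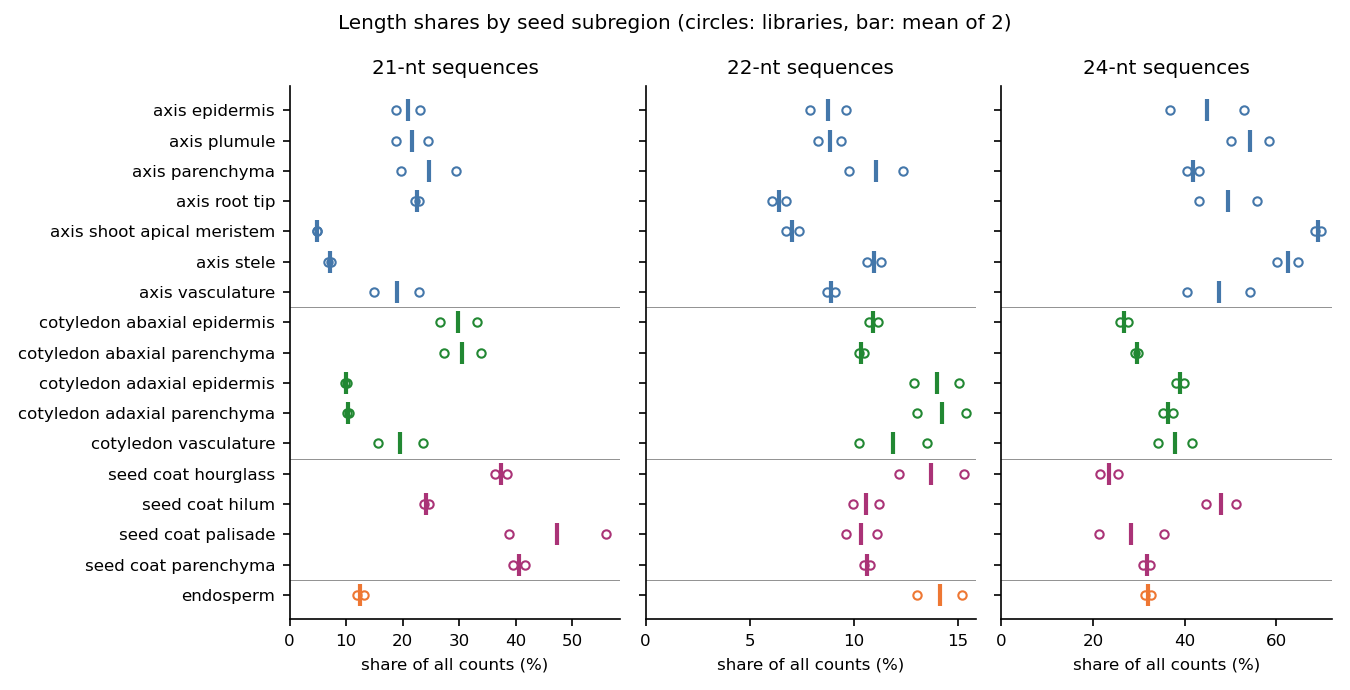
Share of all counts (%, horizontal axis) in 21-, 22- and 24-nt sequences for the 17 subregions (vertical axis), coloured by organ, with a circle for each library and a bar for the mean of 2. The shoot apical meristem, whose libraries were made from 50 ng, lies lowest for 21 nt (4.86%) and highest for 24 nt (69.1%). Every axis subregion lies above every cotyledon subregion for 24 nt.

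Across all subregions, 39 of 39 families and 24254 of 32538 sequences differed in the omnibus edgeR test. miR396, which represses growth-regulating factor genes, spanned the widest range among families seen in every subregion, from 0.851 CPM ± 1.07 (n = 2) in axis vasculature to 1642 CPM ± 141 in the hilum. miR398, which targets copper/zinc superoxide dismutase, ranged from 4.39 CPM ± 0.609 in the palisade to 4146 CPM ± 690.1 in the plumule. The palisade level may be understated, since the starts of miR398 stood at 0.131 of their expected share in palisade 2. How far this carries over to the counts of miR398 is not known. miR167, which represses auxin response factor genes, ranged from 6.64 CPM ± 6.03 in the root tip to 2418 CPM ± 577 in the hilum. Regions from shared plants could make these adjusted p-values too small.

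The comparison of seed coat and embryo asked which families mark the maternal covering of the seed. miR396 was 83.2-fold higher in the seed coat, at 675 CPM ± 671 (SD, n = 4 subregions) against 7.84 CPM ± 6.41 (n = 12), with a log2 change of 6.38 ± 0.27 (SE, 8 and 24 libraries). miR167 was 30.8-fold higher (4.95 ± 0.22), at 1773 CPM against 104 CPM. miR164, which represses NAC-domain genes, was 26.6-fold higher (4.73 ± 0.30), at 223 CPM against 8.15 CPM. miR2111 had 1661 counts in the 8 seed coat libraries and 10 in the 24 embryo libraries, a ratio of 392 (95% counting interval 212 to 818). miR398 and miR3522 went the other way, with log2 changes of -3.39 ± 0.29 (126 CPM against 979 CPM) and -3.90 ± 0.30 (54.0 CPM against 891 CPM).

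Of 39 families, 21 rose and 6 fell. In the development list 6 of 9 tested members rose and 1 fell, and 6 and 1 adjusted over the list alone. Besides miR396 and miR164, miR394 (5.12 ± 0.47) and miR169 (79 counts against 8, ratio 23.3, interval 11.3 to 55.8) rose, the former aimed at an F-box gene and the latter at nuclear factor Y genes. miR166 rose by 2.184 ± 0.18, from 111155 CPM to 289916 CPM, although it was understated in axis parenchyma 1 and perhaps in seed coat parenchyma. In the nutrient list 4 of 7 rose and 1 fell (4 and 1 adjusted over the list alone). miR395, which acts in sulfate assimilation, changed by 6.48 ± 0.52 and miR2119 by 6.29 ± 0.50, while miR399, which acts in phosphate homeostasis, changed by 1.46 ± 0.44. In the auxin list miR167 and miR393 (5.09 ± 0.52), which represses auxin receptor genes, rose, while miR160 (-1.29 ± 0.42) and the TAS3-derived tasiARF (-1.30 ± 0.52) fell, which made 2 and 2 of 5 (2 and 2 adjusted over the list alone). Among phasiRNA triggers, families that start secondary small RNAs, miR1507 (0.59 ± 0.20), miR1509 (2.27-fold) and miR2118 (0.59 ± 0.21) rose and miR1510 (-0.93 ± 0.37) fell, 3 and 1 of 7 (3 and 1 adjusted over the list alone). In the small RNA pathway list miR168, which represses ARGONAUTE1, rose by 1.09 ± 0.23 and miR1515 by 1.42 ± 0.41, 2 of 4 (2 adjusted over the list alone). Of other legume families 4 of 7 rose, among them miR862 (262 counts against 6, ratio 103, interval 46.7 to 283) and miR1513 (1.54 ± 0.42), and miR3522 fell (4 and 1 adjusted over the list alone). In 8 families every seed coat subregion lay above every embryo subregion, which chance gives in 0.0549% of groupings for a family. These were miR396, miR167, miR164, miR2111, miR862, miR2119, miR395 and miR169.

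Among single sequences 4860 rose and 4175 fell. Of the 21-nt sequences 27.6% rose and 12.8% fell, while of the 25- and 26-nt sequences 5.71% rose and 20.5% fell. The 21-nt sequence AAACCACAGGTGAAGGACTTG had 10765 counts in the seed coat and 9 in the embryo (ratio 2821, interval 1486 to 6171), and was highest in the palisade. TAGGACTTGAGAACCCCGCCT, highest in seed coat parenchyma, had 6259 against 2 (ratio 7381, interval 2043 to 60964), and AAGATAGACACACCCTTGGGC, highest in the hilum, had 4914 against 5 (ratio 2318, interval 993 to 7142). The largest falls were those of the 24-nt sequence TGGTTGAGGAGCGTGAGAAGGATT (-7.47 ± 0.49) and of the 22-nt sequences CAATGGCCGCCTGAACCCCGAG (-7.45 ± 0.53) and CGCCATATCCCTTGCCTTGCCT (-7.33 ± 0.51). With library totals in place of TMM the split turned to 3304 rose and 6803 fell, and the median change of all sequences moved from -0.14 to -0.51. Of the families, 16 then rose and 9 fell.

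With limma on subregion means, where the 4 and 12 subregions are the replicates, 13 families passed: miR396, miR167, miR164, miR2111, miR2119, miR395, miR862, miR394, miR169, miR393, miR1515, miR398 and miR3522. miR166 (log2 2.20) did not pass there, and 3995 sequences passed. Without seed coat palisade 2 the changes of miR399, miR169 and miR393 could not be tested, since the palisade and at least 1 embryo subregion then had no count of them. With library totals miR1507 (0.15) and miR2118 (0.17) did not, and in DESeq2 miR862 (6.76) did not. miR156/miR157 (-0.49 ± 0.23) passed in only 8 of 15 settings, the reported one included, and missed the threshold in 22 of 34 leave-outs, and miR1510 and tasiARF missed it in 4 each. The edgeR p-values take libraries as independent, and they are too small if captured regions came from the same seeds.

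**Figure D2:**
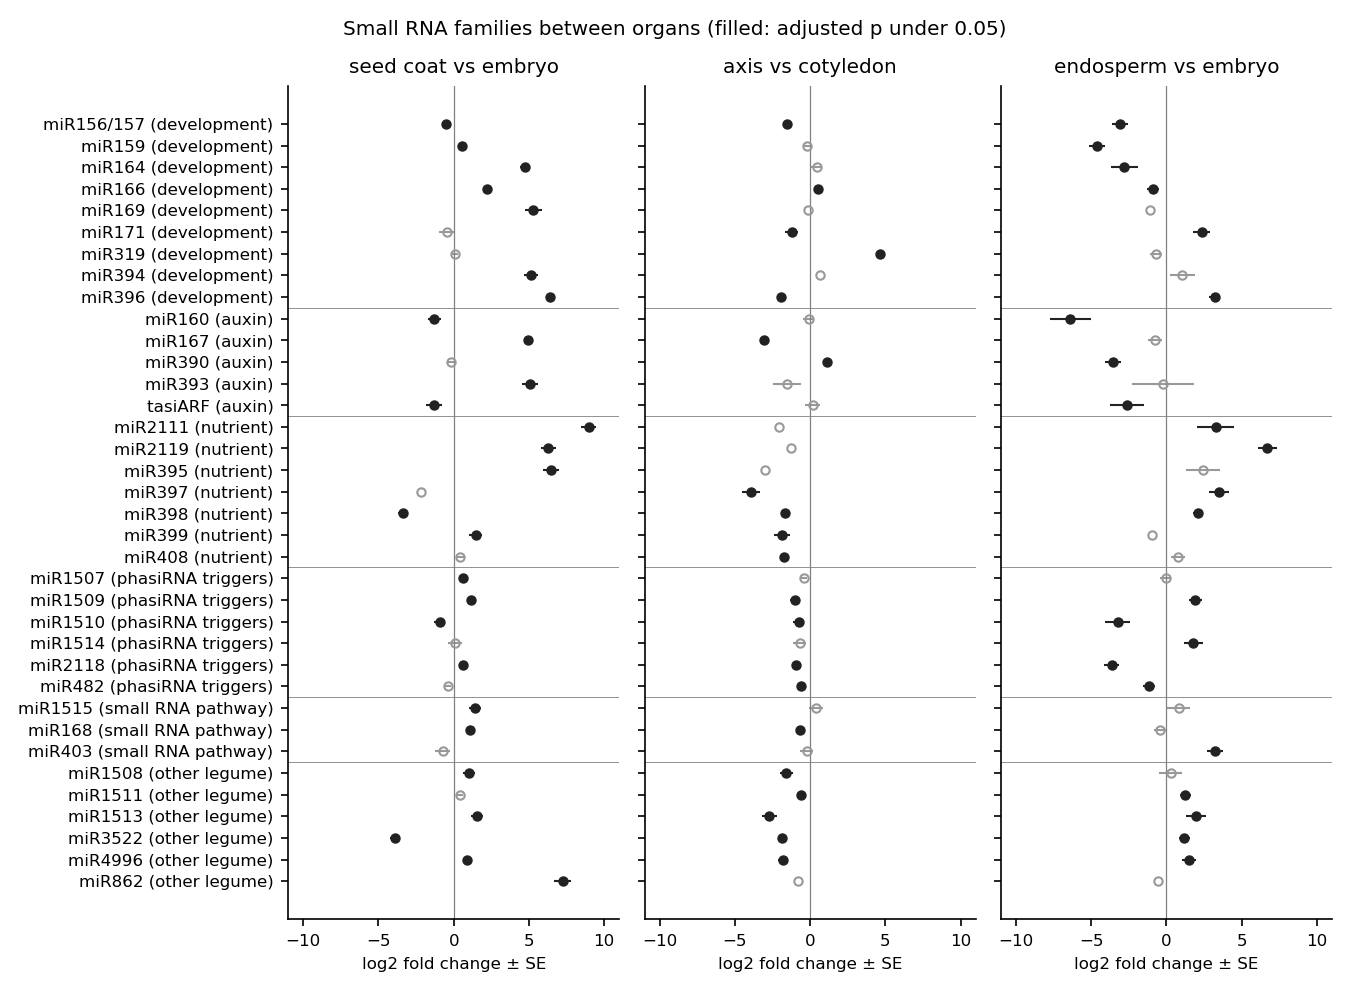
Log2 fold change with its SE (horizontal axis) of each family that passed in at least 1 of 3 organ contrasts (vertical axis, grouped by list), with filled points for an adjusted p under 0.05 and open grey points for the rest. Points without a bar have an SE wider than the axis, and miR2111 (8.96) lies farthest to the right for seed coat against embryo.

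The comparison of axis and cotyledon contrasted the future root and shoot with the storage organs. miR319, which represses TCP genes, was 25.5-fold higher in the axis, at 3124 CPM ± 1784 (SD, n = 7) against 191 CPM ± 182 (n = 5), with a log2 change of 4.67 ± 0.27 (SE, 14 and 10 libraries) and every axis subregion above every cotyledon subregion. miR390, which starts tasiARF production from TAS3 transcripts, was 2.22-fold higher (1.15 ± 0.23), at 2311 CPM against 1065 CPM. The cotyledons held more of miR167 (-3.06 ± 0.25, 41.0 CPM in the axis against 193 CPM), miR3522 (-1.88 ± 0.23, 523 CPM against 1407 CPM) and miR156/miR157 (-1.51 ± 0.22, 949.5 CPM against 1828 CPM), the last of which represses SPL genes.

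Of 39 families 3 rose and 18 fell. In the nutrient list 4 of 7 fell and 0 rose in the edgeR test (4 and 0 adjusted over the list alone), among them the copper-linked families miR398 (-1.65 ± 0.23), miR408 (-1.73 ± 0.28) and miR397 (-3.92 ± 0.62). The other members, miR395, miR2111 and miR2119, had an empty subregion on both sides and were outside the test's reach. Of the phasiRNA triggers 4 of 7 fell (4 adjusted over the list alone), among them miR2118 (-0.92 ± 0.22), miR1509 (-1.01 ± 0.30) and miR482 (-0.61 ± 0.21). Of other legume families 5 of 7 fell (5 adjusted over the list alone), among them miR4996 (-1.80 ± 0.31) and miR1513 (-2.72 ± 0.49). The rest, miR862 and miR1512, were outside the test's reach for the same reason. In the development list miR319 and miR166 (0.56 ± 0.20) rose and 3 of 9 fell (2 and 3 adjusted over the list alone). Those that fell were miR156/miR157, miR396 (-1.92 ± 0.31) and the summed forms of miR171 (-1.21 ± 0.43), which represses GRAS-family genes. That sum leaves out a miR171-like sequence that rose in vasculature. The mean of miR166 on the plain scale was lower in the axis, at 106403 CPM ± 71312 (SD, n = 7) against 117808 CPM ± 119458 (n = 5), and it was understated in axis parenchyma 1. In the auxin list 1 of 5 rose and 1 fell (1 and 1 adjusted over the list alone), and in the small RNA pathway list miR168 fell (-0.66 ± 0.24), 1 of 4 (1 adjusted over the list alone). The share of off-size sequences and of 5S ribosomal RNA was also lower in the axis than in the cotyledons (13.01% against 22.9%, and 5.39% against 10.6%).

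Among sequences 4347 rose and 6002 fell. Of 24-nt sequences 18.7% rose and 6.26% fell, while of sequences of 18 to 20 nt 1.16% rose and 56.1% fell. TAGCTGCCGACTCATTCATCCA had 5360 counts in the axis and 1 in the cotyledons (ratio 2156, interval 387 to 85177). CTTGGACTGAAGGGGCCTCTTC, which resembles miR319, rose by 9.87 ± 0.52 and was highest in the stele. With RLE factors 6160 sequences rose and 4779 fell (7364 and 5276 in DESeq2), and the median change moved to 0.20. In limma on subregion means 2 families, miR319 and miR167, and 3467 sequences passed. With RLE miR482 (-0.36), miR168 (-0.44) and miR171 (-0.98) did not pass, and miR397 (-3.07) did not without cotyledon vasculature 2, nor miR168 without adaxial epidermis 1 (-0.38), adaxial parenchyma 2 (-0.52) or cotyledon vasculature 1 (-0.49). In all, miR168 passed in 7 of 15 settings. Without the 50 ng libraries 14 families passed, miR482, miR1509 and miR2118 no longer among them, and as regions from 1 plant are not independent, the edgeR p-values may be too small here too.

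The comparison of endosperm and embryo rests on 2 endosperm libraries against 24 of the embryo. miR159 was 24.2-fold lower in the endosperm, at 199 CPM against 5648 CPM ± 2665 (SD, n = 12 subregions), with a log2 change of -4.59 ± 0.53 (SE). miR2118 (-3.65 ± 0.53), miR390 (-3.56 ± 0.54) and miR156/miR157 (-3.07 ± 0.53) were also lower, and miR160, which represses auxin response factor genes, had 1 count against 3522 (ratio 271, interval 48.5 to 10689). The endosperm held more miR2119 (6.69 ± 0.63, 18.05 CPM against 0.330 CPM), more miR396 (3.198 ± 0.39, 47.7 CPM against 7.84 CPM) and more miR403, which represses ARGONAUTE2 (3.24 ± 0.55, 37.7 CPM against 4.94 CPM). miR398 was 4.29-fold higher (2.10 ± 0.33).

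Of 39 families 13 rose and 10 fell. Of the nutrient list 4 of 7 rose and 0 fell in the edgeR test (5 and 0 adjusted over the list alone). They included miR397 (3.47 ± 0.66) and miR2111, which rests on 4 counts: its unscaled level was 0.436 CPM in the endosperm and 0.0837 CPM in the embryo, from 4 and 10 counts. Of other legume families 4 of 7 rose (4 adjusted over the list alone), with miR1511 (1.26 ± 0.35) and miR3522 (1.20 ± 0.37) as the most abundant. In the development list 2 of 9 rose, miR396 and the summed forms of miR171 (2.33 ± 0.59), and 4 fell (2 and 4 adjusted over the list alone). The sum for miR171 leaves out a miR171-like sequence. Those that fell included miR164 (6 counts, ratio 14.2 in favour of the embryo, interval 6.49 to 38.7) and miR166 (-0.89 ± 0.38). miR166 missed the threshold with the start offset (-0.50) and when families were fitted with the sequences (-0.89). It stood at -0.79 without the 14 libraries with missing starts. In the auxin list 3 of 5 fell (3 adjusted over the list alone): miR390, miR160 and tasiARF (4 counts against 1451, ratio 27.9, interval 10.9 to 102). Among phasiRNA triggers miR1509 (1.93 ± 0.45) and miR1514 (1.79 ± 0.64) rose and miR2118, miR1510 (-3.24 ± 0.84) and miR482 (-1.16 ± 0.41) fell, 2 and 3 of 7 (2 and 3 adjusted over the list alone). In the small RNA pathway list miR403 rose, 1 of 4 (1 adjusted over the list alone). The off-size share (28.6%) and the 5S ribosomal share (16.9%) of the endosperm were the highest of the 4 organs.

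Among sequences 8069 rose and 6169 fell. Of 18- to 20-nt sequences 49.1% rose, and of 24-nt sequences 26.8% fell. CTTACAGAGAATGGAGCGCCT reached 7319 CPM in the endosperm against 9.31 CPM in the embryo (12.91 ± 0.52), and AATAGAACAAACTAAACACCT reached 994 CPM against 0.646 CPM (13.76 ± 0.54). TGAGTTGGGTGGTAACGGGGA had 5 endosperm counts against 23766 (ratio 365, interval 156 to 1125). The median change of all sequences was -0.74, and with library totals it was -1.37, with 6080 sequences that rose and 9018 that fell (6216 and 7939 in DESeq2), and 8 families that rose and 12 that fell. Without endosperm 2, 15 families and 7018 sequences passed, with miR166 (-0.63), miR2111 (2.58), miR1509 (1.35), miR1514 (0.20), miR1511 (1.04) and miR3522 (1.084) no longer among them. Without endosperm 1, 9462 sequences passed, and miR164 (-1.95), miR166 (-1.21), tasiARF (-1.81) and miR482 (-0.72) did not. A lone library is then assumed to vary like the other subregions, and both endosperm captures may stem from few seeds, which would make the p-values too small.

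The comparison of epidermis and parenchyma asked what sets the outer cell layer of the embryo apart from the tissue beneath it. miR168 was 7.21-fold lower in the epidermis, at 130 CPM ± 130 (SD, n = 3 places) against 603 CPM ± 74.2, with a log2 change of -2.85 ± 0.37 (SE, 6 and 6 libraries). miR1510 (-2.83 ± 0.51, 25.5 CPM against 111 CPM) and miR160 (-2.75 ± 0.57, 6.94 CPM against 38.5 CPM) had lower means in the epidermis at all 3 places. On the adaxial face the libraries overlapped for miR1510, at 13.5 to 103 CPM in the epidermis against 89.1 to 94.0 CPM in parenchyma. One of these epidermis libraries is near-identical to a parenchyma library. miR2109 had 8 epidermis counts against 54 (ratio 7.78 in favour of parenchyma, interval 3.68 to 18.9). miR398 fell by 0.93 on the log2 scale, at 993 CPM against 1064 CPM, although in the abaxial cotyledon it stood at 2076 CPM in the epidermis against 1323 CPM.

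Of 39 families 0 rose and 5 fell in edgeR. At an unadjusted p under 0.05 there were 10 families, and 9 fell and 0 rose in DESeq2. By list, phasiRNA triggers gave 2 falls of 7 (2 adjusted over the list alone), the auxin list 1 of 5 (1 adjusted over the list alone), and the nutrient list 1 of 7 (1 adjusted over the list alone). The small RNA pathway list gave 1 of 4 (2 adjusted over the list alone, with miR162, -1.19 ± 0.51). In the development list 0 of 9 passed, and of the other legume families 0 of 7 (0 and 0 adjusted over the list alone in edgeR). Among sequences 2433 rose and 2587 fell. Of 18- to 20-nt sequences 17.97% rose and 9.07% fell. AAATGTCTCTCTGAGCTCT rose by 5.20 ± 0.76 to 701 CPM. The largest falls, such as that of GCGAGAATGTCGGCTTGA (-7.87), were of sequences whose own starts are missing or thinned in epidermis files, so they cannot be read as tissue differences. Fragments of 5S ribosomal RNA took a larger mean share in the epidermis at all 3 places. In the axis it was 9.02% ± 4.04 (SD, n = 2 libraries) against 5.55% ± 0.199, and on the abaxial face 13.7% ± 1.23 against 6.30% ± 0.644. The adaxial face gave 12.4% ± 6.53 against 10.5% ± 3.62, but its 2 near-identical libraries gave 7.81% (epidermis 1) and 7.93% (parenchyma 1).

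Starts were missing from 5 of the 6 epidermis libraries, adaxial epidermis 1 being the exception, and from 1 of the 6 parenchyma libraries. Of the sequences that fell, 72.6% began with a start thinned in the epidermis files, against 19.2% of all tested. All 5 families that fell have starts thinned in the epidermis files, by log2 -1.58 for miR398, -1.21 for miR1510, -1.14 for miR2109, -0.94 for miR160 and -0.86 for miR168. Starts were also thinned for families that did not pass, most of all miR164 (-1.57, family change -1.06) and miR1513 (-1.03, family change -0.48). Others were miR1507 (-0.72), miR3522 (-0.69) and miR162 (-0.66). With start composition as an offset 2547 sequences passed (1639 rose, 908 fell), and 7 families did (2 rose, 5 fell). miR168 (-2.06), miR160 (-1.86), miR1510 (-1.75) and miR2109 (-3.64) were among these, while miR398 turned to 0.67 and no longer passed. miR398 also missed the threshold in several leave-outs, such as that of adaxial epidermis 2 (-0.87). Adaxial epidermis 1 was near-identical to adaxial parenchyma 1, and its deposited name carries the parenchyma code, so only adaxial epidermis 2 is an independent adaxial epidermis sample: 1798 sequences passed without it (2749 without axis epidermis 2, 3064 without abaxial epidermis 1), and 4 families and 7168 sequences passed without the near-identical library. The split was 1668 rose and 2970 fell with library totals, 1766 and 3016 with RLE, and 2344 and 3670 in DESeq2. In 9 families (RLE) or 8 (library totals) the call was a fall, and p-values would be too small if layers came from the same seeds.

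**Figure D3:**
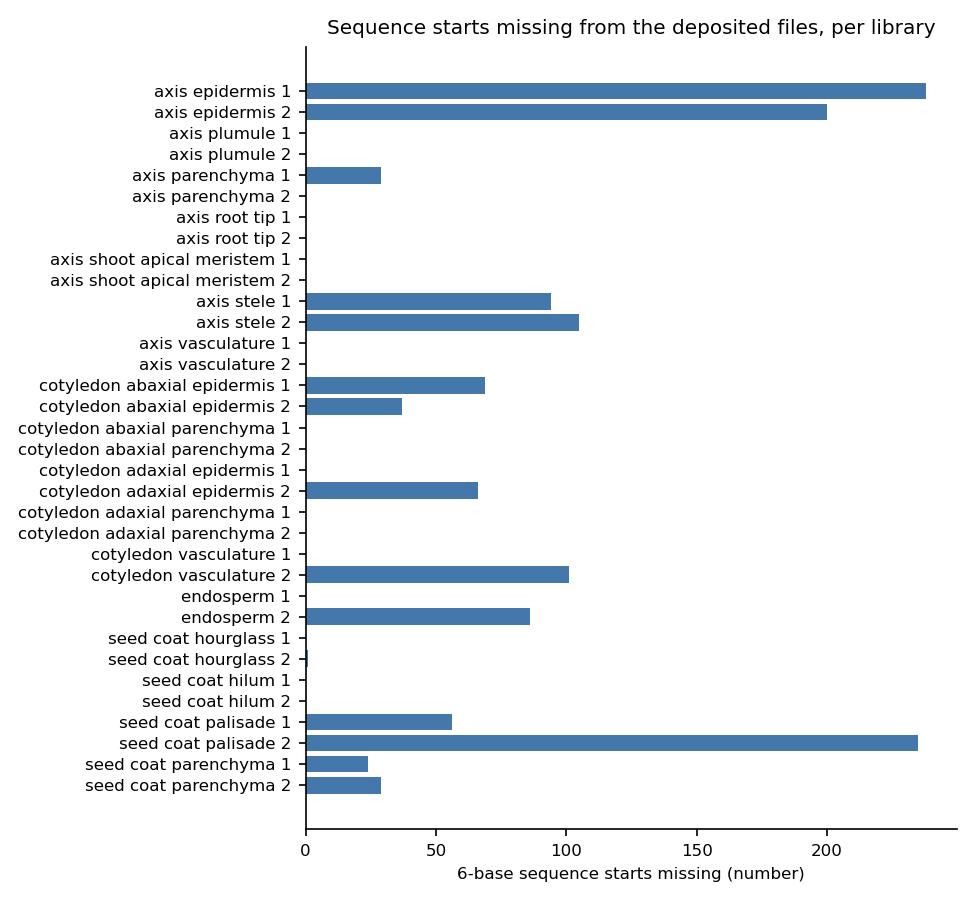
Number of 6-base sequence starts below 10% of the expected number (horizontal axis) in each of the 34 deposited libraries (vertical axis, subregion and replicate number). The bars reach 238 in axis epidermis 1, and 19 libraries have none.

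The comparison of vasculature and parenchyma asked which families mark the conducting tissue of the embryo. miR394 was higher in vasculature, with 44 counts in 4 libraries against 6 in 6 libraries of parenchyma (ratio 6.20, interval 2.63 to 17.8), of which 5 had no count. The summed forms of miR171 were 6.30-fold lower in vasculature (-2.65 ± 0.75, SE), at 1.48 CPM ± 0.923 (SD, n = 2 organs) against 8.49 CPM ± 2.35 (n = 3 subregions), but a more abundant miR171-like sequence outside the sum rose. miR1510 (-1.83 ± 0.57, 41.3 CPM against 111 CPM), miR390 (-1.35 ± 0.37, 659.8 CPM against 1643 CPM) and miR398 (-1.20 ± 0.38, 446 CPM against 1064 CPM) were lower as well. miR2109 (-2.34 ± 0.79) and miR1509 (-1.33 ± 0.50) completed the 6 families that fell.

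By list, phasiRNA triggers gave 3 falls of 7 (4 adjusted over the list alone) and the nutrient list 1 of 7 (1 adjusted over the list alone). The development list gave 1 rise and 1 fall of 9 (1 and 2 adjusted over the list alone), and the auxin list 1 fall of 5 (1 rise and 3 falls adjusted over the list alone). The small RNA pathway list gave 0 of 4 in edgeR, and 3 falls adjusted over the list alone; among them was miR168 at -0.92 ± 0.40. Of other legume families 0 of 7 passed (0 adjusted over the list alone). Over all families 21 had an unadjusted p under 0.05. Among sequences 387 rose and 189 fell, and TTGAGCCGCGCCAATATCACT, which resembles miR171 but holds none of its cores, rose by 5.54 ± 0.63 to 61.7 CPM. AGACGACTTTAGAATACTGTAAGT rose by 3.90 ± 0.52, while CCCGGGCGACTGTTTACCAAA fell by 4.01 on the log2 scale. In DESeq2 583 sequences rose and 660 fell, and with RLE 293 and 217.

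These counts moved with single libraries. Without axis parenchyma 1 there were 4 families and 76 sequences, without axis vasculature 1 there were 4 and 294, and without axis vasculature 2 there were 11 and 1462. Without axis parenchyma 2 there were 13 and 355, without cotyledon vasculature 2 there were 12 and 261, and without root tip 1 or root tip 2 there were 12 families. Sequences came to 290 without cotyledon vasculature 1, and to 912 and 899 without adaxial epidermis 1 and 2. Without axis parenchyma 1 miR171 (-1.91), miR1510 (-1.29), miR2109 (-1.56) and miR1509 (-0.99) did not pass. miR2109 also missed the threshold with no level filter (-2.34), with low-complexity libraries left out (-1.96) and in several other leave-outs, and miR398 did not without axis parenchyma 2 (-0.94), axis vasculature 1 (-0.94) or cotyledon vasculature 2 (-1.03). miR1509 missed it in 21 of 34 leave-outs, with the start offset (-1.31), with 1 of the near-identical libraries left out (-1.29) and with low-complexity libraries left out (-1.05). Without the 14 libraries with missing starts 20 sequences passed, and of the 8 families that then passed only 3 were among the 7 above, while miR394 (4.41), miR171 (-2.11), miR1510 (-1.14) and miR2109 (-1.71) did not pass. Vascular and parenchyma captures from 1 set of plants would not be independent, and the p-values would be too small.

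The comparison of shoot and root tip set plumule and shoot apical meristem against the root tip. miR398 (2.84 ± 0.56, SE, 4 and 2 libraries), miR408 (3.44 ± 0.70) and miR3522 (2.65 ± 0.56) were higher in the shoot, at 2217, 194 and 915 CPM against 153, 12.0 and 85.8 CPM. miR167 was 6.39-fold higher (2.68 ± 0.60). The summed forms of miR171, which leave out the miR171-like sequence, had 524 counts against 10 (ratio 16.9, interval 9.10 to 35.4). miR396 was 10.4-fold lower in the shoot (-3.37 ± 0.61), at 1.29 CPM ± 0.0323 (SD, n = 2 subregions) against 13.6 CPM. miR164 (-2.12 ± 0.67) and tasiARF (-3.25 ± 0.83) were lower too.

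Of 39 families 7 rose and 5 fell. By list, the nutrient list gave 2 rises of 7 (2 rises and 1 fall adjusted over the list alone), and other legume families gave 2 rises of 7, miR3522 and miR4996 (2 adjusted over the list alone). The auxin list gave 1 rise and 2 falls of 5 (1 and 2 adjusted over the list alone). The development list gave 1 rise and 3 falls of 9 (1 and 3 adjusted over the list alone), with miR166 at -2.09 ± 0.40. Among phasiRNA triggers miR1507 rose (1.23 ± 0.45), 1 of 7 (1 adjusted over the list alone), and in the small RNA pathway list 0 of 4 passed in edgeR (0 adjusted over the list alone). Among sequences 284 rose and 222 fell. Of 22-nt sequences 3.23% rose and 0.565% fell. ATGTTCTCACGTCATGGCTGCC rose by 4.22 ± 0.70, to 321 CPM from 16.5 CPM, and TCAGTGGATAGTGATACAGGG fell by 4.92 on the log2 scale.

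Both shoot apical meristem libraries were made from 50 ng, so leaving out the 50 ng libraries left the plumule alone against the root tip and could not part RNA input from subregion. miR166 then stood at 0.10 and miR390 at 0.92, with signs opposite to those above, while tasiARF (-1.61), miR164 (-1.91) and TCAGTGGATAGTGATACAGGG (-2.29) did not pass. Without root tip 1 miR171 (3.32), miR4996 (2.176) and miR1507 (0.73) did not pass, and without root tip 2 tasiARF (-2.20), miR164 (-1.36) and miR390 (-1.26) did not. miR1507 passed in only 7 of 14 settings, the reported one included, with DESeq2 (1.15), library totals (0.74) and the file name covariate (0.89) among those where it missed, and it missed in 7 of 34 leave-outs. Sequences came to 56 without root tip 1, and without root tip 2 there were 2036. The count was 221 and 299 without plumule 1 and 2, 218 and 197 without shoot apical meristem 1 and 2, and 765 and 870 without axis vasculature 1 and 2. With library totals 254 sequences rose and 955 fell (259 and 325 with RLE), and the median change moved from 0.14 to -0.17. The 2 root tip libraries, and regions dissected from the same axes, limit what these p-values can carry, since they may be too small.

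The comparison of the adaxial and abaxial faces of the cotyledon asked whether families known from leaf polarity differ between the faces. miR166 was 55.8-fold lower on the adaxial face (-5.80 ± 0.42, SE, 4 and 4 libraries, 2 of the adaxial ones near-identical, which makes the SE too small), at 4280 CPM ± 812 (SD, n = 2 subregions) against 238698 CPM ± 43104. tasiARF, which represses auxin response factor genes, was 15.4-fold higher on the adaxial face (3.94 ± 0.86), at 20.1 CPM against 1.97 CPM. Its trigger miR390 was 6.28-fold higher (2.65 ± 0.40), at 2147 CPM ± 221 against 347 CPM ± 90.0. miR319 was 8.70-fold lower (-3.12 ± 0.41) and miR408 2.55-fold lower (-1.35 ± 0.48). In the epidermis miR166 stood at 3706 CPM against 269177 CPM, and in the parenchyma at 4854 CPM against 208219 CPM.

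Of 39 families 2 rose and 3 fell. The auxin list gave 2 rises of 5 (2 adjusted over the list alone), the development list 2 falls of 9 (2 adjusted over the list alone), and the nutrient list 1 fall of 7 (2 adjusted over the list alone, with miR397, -1.84 ± 0.71). Of phasiRNA triggers 0 of 7, of other legume families 0 of 7 and of the small RNA pathway list 0 of 4 passed in edgeR (0 adjusted over the list alone); over all families 9 had an unadjusted p under 0.05. The families took up 4.06% ± 0.155 and 4.13% ± 0.0404 of counts in the adaxial epidermis and parenchyma (n = 2 libraries each), against 26.2% ± 5.34 and 26.2% ± 5.37 on the abaxial face. Among sequences 35 rose and 65 fell. GGAATGTTGTCTGGCTCGAGG, the other strand of the miR166 hairpin, fell by 5.82 on the log2 scale, and GGAATGTTGGCTGGCTCGAGG by 6.41. The 24-nt sequence AGATGGTTGAGGAGCGTGAGAAGG rose by 3.69 ± 0.58, to 5479 CPM from 423 CPM.

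The 2 near-identical libraries both lie on the adaxial side, and with 1 of them left out 4 families and 82 sequences passed, and miR408 (-1.35) was the family that no longer passed. miR166 then stood at -5.99, tasiARF at 4.15, miR390 at 2.68 and miR319 at -2.90. miR408 also missed the threshold with library totals (-0.93), RLE (-1.23), the start offset (-1.26) and without the 14 libraries with missing starts (-0.98), and in 11 of 34 leave-outs. Without adaxial epidermis 2, 239 sequences passed, and without the 14 libraries with missing starts tasiARF stood at 2.27 and did not pass. With library totals 65 sequences rose and 56 fell (85 and 77 in DESeq2), the median change of all sequences moved from 0.08 to 0.50, and 3 families rose and 2 fell. With 2 subregions a side, all adaxial subregions lie above all abaxial ones in 16.7% of groupings by chance, and p-values may be too small where both faces came from 1 seed.

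**Figure D4:**
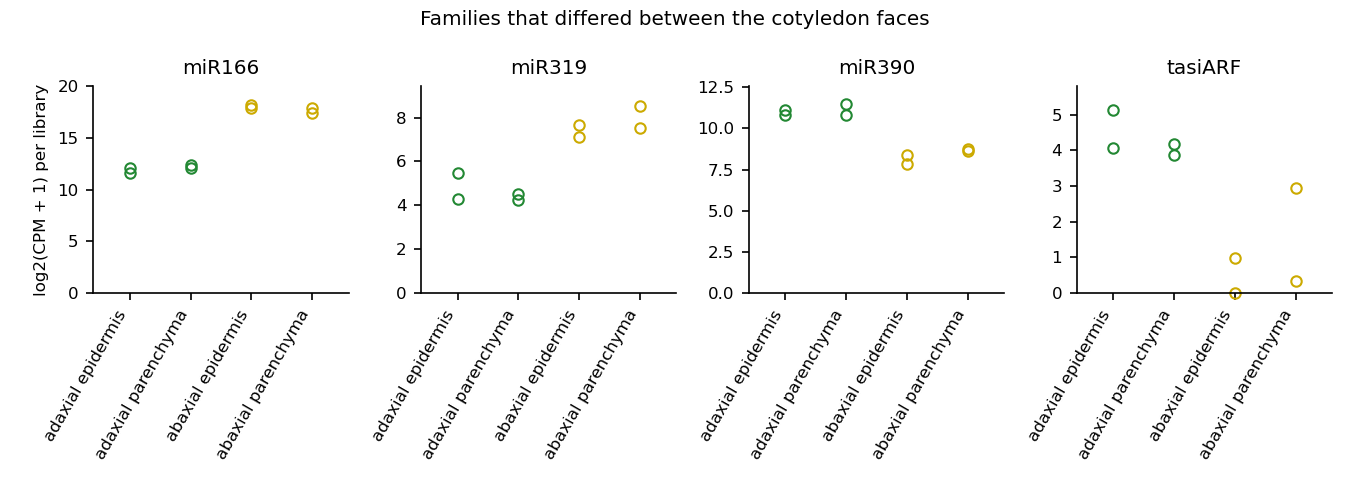
Level of 4 families, as log2 of CPM plus 1 (vertical axis), in the libraries of the adaxial and abaxial epidermis and parenchyma of the cotyledon (horizontal axis), with a circle for each library and 2 libraries per subregion. miR166 and miR319 lie lower and miR390 and tasiARF higher on the adaxial face, while adaxial epidermis 1 and adaxial parenchyma 1 are near-identical libraries.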

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

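The tests of sequence starts on the epidermis families and on the miR166 forms, both tests of the near-identical libraries, and the fits with a start offset or with a near-identical library left out were chosen after the result was seen. In 4 families the effect of tissue differed between axis and cotyledon by the interaction test in edgeR. Epidermis against parenchyma, miR398 changed by -3.07 in the axis and stood at 0.14 in the cotyledons, a difference of -3.20 (log2, adjusted p = 0.000280). miR168 changed by -4.64 and -1.96, a difference of -2.69 (adjusted p = 0.00702). With start composition as an offset these differences were -1.20 and -1.52 and neither passed, and with 1 of the near-identical libraries left out that of miR168 was -2.16 and did not pass. Vasculature against parenchyma, miR319 stood at -1.51 in the axis and 2.60 in the cotyledons, a difference of -4.11 (adjusted p = 6.39e-07), which was -4.50 with the start offset. miR166 stood at -0.66 and 1.70, a difference of -2.36 (adjusted p = 0.00394), which was -4.28 with the start offset, -2.81 without axis parenchyma 1 and, no longer passing, -1.70 without axis parenchyma 2. Captured regions may share plants, so these p-values may be too small, and the miR166 difference moved to -4.28 once starts were allowed for. Cotyledon parenchyma was here the mean of 2 faces that differed widely. It held 4854 CPM of miR166 and 20.1 CPM of miR319 adaxially, against 208219 and 278 CPM abaxially. The TCGG form of miR166 stood at 85518 CPM in cotyledon vasculature, between 192546 (abaxial) and 4048 CPM (adaxial) in parenchyma. The cotyledon values thus depend on averaging the faces, and an opposite effect on miR166 in the 2 organs cannot be read from them.

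Among the 8 seed coat libraries, hourglass 2 stood apart with 15.3% of its counts in 22-nt sequences (Wilson 95% interval 15.2 to 15.3), while the next highest, hourglass 1, had 12.2%. The test covered 16 ends of groups, so 1 such library can arise by chance.

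The first pattern was the loss of sequences that begin with certain bases from single files, and across 21- and 22-nt sequences the change between epidermis and parenchyma went with the change of their start among 23- and 24-nt sequences (rho = 0.386, across sequences, which are not independent replicates), so missing starts are a candidate source of part of these calls. Across the 39 families the same measure was 0.419 (permutation p = 0.00871), between the bounds set for it. For families tissue and missing starts thus cannot be told apart, because 5 of 6 epidermis files but only 1 of 6 parenchyma files lost starts. All 5 families that fell had thinned starts, as had some that did not pass, and 4 of the 5 passed with the start offset. In both seed coat parenchyma libraries and axis parenchyma 1, the start TCGGAC among 23- and 24-nt sequences stood at 0.159 or less of the level expected from other libraries. The 2 leading miR166 forms are 21 nt long, but longer variants of miR166 were not removed from this measure. A lack of the TCGG form could therefore also lower it. The lowest of the other 31 libraries was at 0.387. That fits starts thinned in files, but with this thinning undone the TCTC form still made up 99.966% or more of the 2 forms in seed coat parenchyma, against 94.3% at most in the other 31 libraries, so the measured thinning is too small for the share of 99.997%. In axis parenchyma 1 it was also too small (99.7% against 56.4% in the replicate from the same tissue), so the measure misses part of the loss, and for seed coat parenchyma a tissue's choice of miR166 form and removal of starts cannot be told apart.

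The second pattern was the likeness of cotyledon adaxial epidermis 1 and adaxial parenchyma 1, whose totals differed (3110448 and 2341506 counts). Their chi-square per degree of freedom was 1.49965, against 20.8 or more in replicate pairs and 44.7 or more in other pairs, which is what 1 library deposited under both labels may give. An epidermis library kept under the parenchyma label would lie closer to adaxial epidermis 2. The pair correlated with adaxial parenchyma 2 at r = 0.905 and with adaxial epidermis 2 at 0.681, a difference of -0.224. However, adaxial epidermis 2 had 66 missing starts, while the pair and adaxial parenchyma 2 had 0. Missing starts could lower r whatever the tissue, so these values cannot decide which label is wrong. The parenchyma code in the deposited name of adaxial epidermis 1 goes with a parenchyma library under the epidermis label, while 2 sequencing runs of 1 library stay open and untested. No biological explanation was tested.

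The third pattern was the opposition of the cotyledon faces, with miR166 and miR319 lower and miR390 and tasiARF higher on the adaxial side. Thinned starts were argued against, for families (the median ratio of start change to family change was -0.0131) and for sequences (rho = 0.0765). The near-identical libraries were argued against as the cause, since 4 of the 5 families passed with 1 of them left out. Over 34 splits of the 8 libraries the real one gave 5 families and the highest other gave 0, so 1 was as large, but with near-identical libraries and 2 subregions a side (16.7% by chance for a family) chance is not excluded at the level of subregions. A biological difference between faces stays open beside it, with the plants behind each face unknown and only 3 distinct adaxial libraries.

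Other splits of the samples were fitted for each comparison with at least 3 units a side, in fits of those libraries alone where libraries were regrouped. There the libraries were taken as independent units, which replicates of a subregion and near-identical libraries are not. For seed coat against embryo chance could be excluded if subregions are independent, with 2 of 100 splits as large for families (27 in the real split, 27 in the highest other). For sequences it was 1 of 100 (9035 and 7765). The median of the other splits was 13 families and 1817 sequences. For axis against cotyledon chance could be excluded on the same terms for sequences (1 of 100, 10349 and 8022) but not for families (7 of 100, 21 and 25). The median there was 11 families and 973 sequences. For epidermis against parenchyma few splits of libraries were as large, for families (1 of 60, 6 and 5) and for sequences (2 of 60, 5318 and 7453). The larger split set both near-identical libraries with axis and abaxial parenchyma, and adaxial parenchyma 2 with the epidermis. It thus kept all 5 epidermis libraries with missing starts on 1 side and gave more calls than the real split. Since libraries are not independent and missing starts went with the layer, these splits exclude neither chance nor missing starts. For vasculature against parenchyma 1 of 60 splits of libraries was as large for sequences (464 and 326) and 6 of 60 for families (2 and 4). In this fit of the vasculature and parenchyma libraries alone the real grouping thus gave 2 families, against 7 in the fit of all 34 libraries. For families all 5 other splits as large grouped both adaxial parenchyma libraries. Chance was thus not excluded for families, and for sequences only if libraries were independent, which they are not. For adaxial against abaxial sequences chance could not be excluded (2 of 34, 92 and 234). The larger split exchanged adaxial epidermis 2 for abaxial parenchyma 1, which points to a structure in the libraries that the faces do not give. It set libraries without missing starts against a side with adaxial epidermis 2 and abaxial epidermis 1 and 2 (66, 69 and 37 missing starts) and abaxial parenchyma 2. Whether missing starts made this split larger was not tested.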

How the results depend on the processing

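Start offset, near-identical, low-complexity and missing-start settings, and families fitted with the sequences, were chosen after the data were seen; the tests in all other settings were planned. Single items were followed only if they were families that passed in the reported fit or sequences picked for naming by their large changes. Leave-outs apart, 1213 of 1343 family values kept their direction and side of the threshold, 127 lost the call and 3 reversed. Of the sequence values 506 of 521 kept theirs and 15 lost the call. These shares do not measure the stability of sequence calls in general, whose counts moved more widely, as given below. Of 250 values of the counts and shares 210 stayed within bounds. Where no reason is given the cause was not tested.

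Families that passed came to 13 (seed coat) and 2 (axis) with limma on subregion means, which has fewer units. For epidermis they came to 9 with DESeq2, 9 with the file name style as covariate, 8 with library totals and 9 with RLE. For vasculature they came to 13 with DESeq2, 23 with the covariate, 16 with RLE and 4 with the start offset, and for the cotyledon faces to 11 with the covariate and 9 without the 5 low-complexity libraries.

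Sequences, at minimum levels of 2 and 20 CPM, which change how many are tested, came to 56276 and 5678 among subregions, 17019 and 2794 for seed coat, 21363 and 2591 for axis, and 21514 and 3635 for endosperm. At 20 CPM they came to 2057 for epidermis and 326 for vasculature. With limma they came to 3995 for seed coat and 3467 for axis. With DESeq2 they came to 1243 for vasculature, 1436 for shoot and 162 for the cotyledon faces, and with the covariate to 3089 for epidermis and 176 for the faces. The start offset gave 2547 for epidermis, library totals 1209 for shoot, and 1 near-identical library less 912 for vasculature. Without the 5 low-complexity libraries shoot had 160, and without the 14 libraries with missing starts endosperm had 7163, vasculature 20 and the faces 64.

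Among shares, axis minus cotyledon, the 21-nt share of distinct sequences was -1.37 and passed. The family share was -0.0243 for distinct sequences and -1.34 within 20 to 24 nt, a change of sign in a difference that passed in neither. The 22-nt share was -3.12 without the 50 ng libraries and did not pass. Reversed families were miR398 in the epidermis at 0.67 with the start offset, and miR166 at 0.10 and miR390 at 0.92 for shoot without the 50 ng libraries.

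With each library left out in turn, miR399 (seed coat) ran from -0.0115 to 1.83, the former without palisade 2, when 2 subregions had no count and the value carries no information. Families ran from 15 (without endosperm 2) to 24 for endosperm, and for vasculature from 4 (without axis parenchyma 1 or axis vasculature 1) to 13 (without axis parenchyma 2). Sequences ran from 7018 (without endosperm 2) to 14956 for endosperm, from 1798 (without adaxial epidermis 2) to 7168 (without adaxial epidermis 1) for epidermis, and from 76 (without axis parenchyma 1) to 1462 (without axis vasculature 2) for vasculature. For shoot they ran from 56 (without root tip 1) to 2036 (without root tip 2), and for the faces from 67 to 239 (without adaxial epidermis 2). The 22-nt share ran from -3.75 to -3.09 and the family share from -0.525 to 1.04, axis minus cotyledon. A lone library left in a subregion is assumed to vary like the other subregions.

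With a replicate block families numbered 37 among subregions, 27 for seed coat, 21 for axis, 23 for endosperm, 5 for epidermis, 7 for vasculature, 13 for shoot and 5 for the faces. Of the 7 for vasculature 6 were among those without the block, miR2109 (-2.32) being the lost call; CTTTCCTTCCTTGTCTATCCC (1.83, faces) was the other. The 136 correlations between subregions of replicate differences ran from -0.420 to 0.574 (median 0.00491), and 42 were over 0.1, so replicate numbers did not pair libraries throughout, and pairing of some subregions is not excluded.

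At the lowest depth, 2341506 counts, 3 counts are 1.28 CPM, so rare families such as miR172 could not be compared.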

Other observations

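The tests of miR166 starts named here were chosen after the result was seen. These levels were ranked across subregions without a test of each ranking. The hilum was the subregion where the most families peaked. miR159 reached 12894 CPM ± 1039.75 (SD, n = 2) there, miR1507 reached 11800.3 CPM ± 824 and miR396 reached 1642 CPM ± 141. miR1512 had 49 counts, all in the 2 hilum libraries, and 0 counts in the 24 embryo libraries. Other seed coat layers led in other families: miR164 reached 448 CPM ± 221 in the palisade, miR408, which targets copper proteins, reached 705 CPM ± 249.7 in hourglass cells, and miR2118 reached 4832 CPM ± 1853 in seed coat parenchyma. miR168 spanned 2269.76 CPM ± 497 in seed coat parenchyma to 22.4 CPM ± 2.40 in the axis epidermis. It may be understated in the axis epidermis, since its starts stood at 0.378 of their expected share in axis epidermis 2.

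Within the embryo, miR319 was highest in axis parenchyma (6329 CPM ± 2357) and lowest in adaxial parenchyma of the cotyledon (20.1 CPM ± 2.88). miR156/miR157 and miR482 peaked in the stele, at 3135 CPM ± 392 and 9329 CPM ± 1525. miR390 peaked in the plumule at 5930.3 CPM ± 4376, with a wide spread between its libraries. miR399 was highest in cotyledon vasculature (23.2 CPM ± 3.95). The endosperm led in miR403 (37.7 CPM ± 28.5), miR1511 (3161 CPM ± 637) and miR1514 (7.97 CPM ± 7.49).

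The form of miR166 differed between subregions. TCTCGGACCAGGCTTCATTCC, the form that begins with TCTC, made up 83.7% ± 11.4 (SD, n = 2) of its sum with TCGGACCAGGCTTCATTCCCC in axis vasculature, 77.1% ± 5.45 in the stele and 0.0685% ± 0.00398 in the palisade. Thinned TCGG starts inflate such shares, in axis parenchyma (78.2%) and perhaps in seed coat parenchyma (99.997%), by an unknown amount. The start TCGGAC also stood at 0.574 and 0.611 of its expected share in the 2 stele libraries, so the share of the stele may be overstated as well. In palisade 2 it stood at 0.496, and with this thinning undone the TCTC share there moved from 0.0713% to 0.0354%. No test compared the subregions.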
